A study of Mus musculus with 36 samples.

How the data were processed

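RNA extracted with TRI reagent from the liver and eWAT of male mice on the LF, HF and HFLF diets was sequenced on an Illumina NovaSeq instrument. Per the labels, reads were processed with STAR (version not given) and the GRCm38.p6 genome. The counting tool, the annotation release and the counting strand are not given in the sources used here. For each tissue the authors deposited a table of counts per gene and a table named RPKM. The deposited counts were raw whole numbers and were not normalized. Each gene kept had a CPM above 0.5 in at least 6 of the 18 libraries of its tissue, tested on the tables. The values in the deposited table named RPKM were not the RPKM of the gene they stood beside. The lengths they implied repeated with a period of 55487 genes down the columns in both tissues, with 100% of the values equal at that period, and only 0.04% of genes had 1 length across libraries. That table was therefore used in 1 alternative only. No columns were left unmapped, and all 36 libraries were used.

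Gene symbols and positions came from the GENCODE M21 annotation of GRCm38, which held 14034 of the 14052 liver and 16668 of the 16690 eWAT genes.

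The design, the gene lists, the rule for naming genes and most alternatives were set before the data were examined. For each tissue, 1 model with the 3 diets as groups and no covariate was fitted in edgeR 4.0.16 (R 4.3.3) by quasi-likelihood with robust estimation and TMM normalization, with 6 libraries per group. Contrasts HF against LF, HFLF against LF and HFLF against HF were tested by F tests with Benjamini-Hochberg adjustment over all genes of the table, at an adjusted p of 0.05. Standard errors of log2 fold changes came from the same model. The difference between tissues was tested as an interaction in 1 fit over the 13206 genes in both tables. Replicate numbers were not used as a block, because the labels do not say what they mark. By correlations between residuals, the own number was the best match in 0 to 2 of 6 libraries between diets of 1 tissue. Between tissues it was the best match in 5 of 6 LF, 2 of 6 HF and 1 of 6 HFLF libraries (r of -0.036 to 0.155), so that tissues of 1 mouse may share a number. The interaction fit did not use the number, but 1 alternative did. No 2 libraries were near copies.

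Gene lists with at least 5 measured members, 37 in liver and 40 in eWAT, were tested with camera from limma 3.58.1 (preset correlation 0.01, voom weights), adjusted over the lists of a comparison. Camera called 9, 9 and 14 lists in liver and 20, 18 and 20 in eWAT (HF against LF, HFLF against LF and HFLF against HF). With a correlation estimated from the data camera called 0 lists in each comparison, with 0, 1, 4, 3, 2 and 2 lists at an unadjusted p under 0.05, and fry called 8, 7, 4, 23, 0 and 16. Members changed were counted from edgeR, over all genes and adjusted over the list alone. Not every list is described, and lists were chosen for the text after their values were seen.

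The genes named were the 6 largest rises and 6 largest falls per comparison among genes with a mean log2 CPM of at least 2, up to 4 members per described list with the smallest p, and a fixed set. The fixed set was Fasn, Scd1, Cd36, Cyp7a1, Cidec, Ppargc1a and Dicer1 in liver and Lep, Adipoq, Mest, Trem2, Fasn, Ppargc1a and Dicer1 in eWAT. Predicted genes and Mup and immunoglobulin segment genes were left out. For interactions the 4 largest differences of each sign were named, and for the overlaps 6 genes called in both comparisons with the smallest larger p. Some of the genes that the rule named are not described, and some items are not reported here.

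On counts simulated at the depth and spread of these libraries, with 200 of the genes changed, edgeR called 47.8% to 53.7% of genes changed 1.5 times in liver and 29.9% to 35.8% in eWAT. It called 68.7% to 76.1% and 58.2% to 59.7% of genes changed 2 times, and 92.4% to 93.9% and 74.2% to 84.8% of genes changed 4 times. It made 3 to 12 false calls per comparison. Overlaps without any effect came from counts simulated with 1 mean per gene in all 3 diets. This was added after the results were seen, since a first simulation, around the mean of the control libraries, gave too few.

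Alternatives were size factors of the DESeq2 type or upper-quartile factors in edgeR, DESeq2 1.42.0, limma voom with quality weights, only genes with 10 counts in enough libraries (filterByExpr), only genes with a mean CPM of at least 5, a fit of only the 2 groups compared, the replicate number as a block, a fit without robust estimation, a log2 fold change of at least 1, limma-trend on log2(value + 0.1) of the table named RPKM, and leaving out each library in turn. Interactions were also tested with TMM per tissue and with limma voom and a correlation within replicate numbers. Fits without liver LF libraries 1 to 4, without liver LF libraries 1 and 2, and without eWAT LF libraries 3, 4 and 5, HF library 1 and HFLF libraries 4 and 6 were added after seeing the data. So were limma voom without that correlation and the splits of the HF libraries for the genes that turned back. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).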

Results

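RNA was sequenced from the liver and the epididymal white adipose tissue (eWAT, the fat pad beside the epididymis) of wild-type C57BL/6 male mice of the founder generation (F0), all 24 weeks old. The mice ate chow until 6 weeks of age and then received 1 of 3 diets. The LF group ate low-fat diet for 18 weeks and the HF group ate high-fat diet for 18 weeks. The HFLF group ate high-fat diet for 9 weeks and then low-fat diet for 9 weeks. The labels list 6 libraries per diet and tissue, 36 in all, while the series text gives 4 to 6 per group. They do not say whether each library came from a separate mouse, or whether the liver and eWAT libraries of 1 number came from 1 mouse.

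The genes in the deposited tables held 11.7 to 23.3 M counts per liver library (median 18.4 M, 18 libraries) and 8.94 to 31.2 M per eWAT library (median 19 M, 18 libraries). Mean counts in liver were 19.7 ± 1.98 M in LF, 17.4 ± 3.33 M in HF and 15.1 ± 2.6 M in HFLF (mean ± SD, n = 6). In eWAT they were 18.7 ± 7.21, 19.3 ± 2.65 and 17.4 ± 5.46 M. Levels are given below in counts per M counts (CPM, mean ± SD, n = 6 libraries), and changes as log2 fold changes ± SE from the fitted model. Genes said to rise or fall passed an adjusted p of 0.05 over all genes. A list's median is that of its genes' log2 fold changes. Positions refer to GRCm38.

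The comparison of HF with LF in liver asked what the high-fat diet changed. Many genes of fatty acid oxidation and of lipid droplets rose in HF. Many genes of the acute-phase response, of protein folding in the endoplasmic reticulum, of heat shock and of the cytosolic ribosome fell. Cd36, a fatty acid transporter, rose from 17.4 ± 9.16 CPM in LF to 102 ± 67.7 CPM in HF (2.56 ± 0.47, adjusted p = 0.00109). Fga, the fibrinogen alpha chain made in the acute phase, fell from 9888 ± 3219 to 3816 ± 721 CPM (-1.37 ± 0.19, adjusted p = 0.000132). edgeR called 4891 of 14052 genes changed, 2295 higher and 2596 lower in HF (2952 and 1869 with upper-quartile factors). All 6 HF libraries lay on the side of the change, against the LF mean, for 38 of the 44 genes named, and the groups did not overlap for 21. Most were named from the same fits, so such counts, here and below, add no evidence.

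In the fatty acid oxidation and PPARalpha target list, 23 of 35 genes rose, 0 fell and 12 did not pass (24 and 0 adjusted over the list alone). Its median was 0.52 (camera adjusted p = 7.01e-10, adjusted p = 0.717 with an estimated correlation). Hadh, an enzyme of mitochondrial beta-oxidation, rose (0.92 ± 0.13, adjusted p = 0.000158), and so did Decr1, which handles unsaturated fatty acids (0.67 ± 0.10). In the lipid droplet and lipid uptake list, 15 of 25 genes rose, 1 fell and 9 did not pass (17 and 1 adjusted over the list alone). Its median was 0.46 (camera adjusted p = 0.000641, adjusted p = 0.717 with an estimated correlation). Fitm1, a protein of lipid droplet formation (1.87 ± 0.33), Fabp2, a fatty acid binding protein (1.26 ± 0.18), and Mogat1, an enzyme of triglyceride synthesis (3.69 ± 0.73), rose. Cidec, a lipid droplet protein, rose (2.17 ± 0.64, adjusted p = 0.016), but did not pass without HF library 1 (1.36). Here and below, values in parentheses after a library are the log2 fold changes without it.

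De novo lipogenesis genes went both ways. Of that list, 3 of 24 genes rose, 5 fell and 16 did not pass (3 and 5 adjusted over the list alone). Its median was 0.01 (camera adjusted p = 0.767). The mean (-0.10) and camera pointed lower, unlike the median. Without HF library 5 camera pointed higher (adjusted p = 0.872, and 0.759 to 0.957 over fits of all libraries). Srebf1, a transcription factor of lipid synthesis, rose (1.24 ± 0.26, adjusted p = 0.00228), while Acaca, which makes malonyl-CoA, fell (-0.75 ± 0.19, adjusted p = 0.0056). Pnpla3 fell (-1.99 ± 0.57), and further without HF library 1 (-3.04). Scd1, the stearoyl-CoA desaturase, fell from 13219 ± 4677 to 6182 ± 5113 CPM (-1.10 ± 0.37, adjusted p = 0.0294). It did not pass without LF libraries 1 or 2 (-0.97 and -0.97) or HF libraries 2, 3, 4 or 5 (-0.97, -1.03, -1.0 and -0.93), and without HF library 1 it stood at -1.67. Fasn, the fatty acid synthase, did not pass (-0.36 ± 0.26).

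In the bile acid synthesis and transport list, 8 of 24 genes rose, 3 fell and 13 did not pass (8 and 4 adjusted over the list alone). Its median was 0.20 (camera adjusted p = 0.255). Cyp8b1, which sets the share of cholic acid, rose (1.12 ± 0.14, adjusted p = 7.05e-05, ENSMUSG00000050445, chromosome 9, 121914356 to 121916305), and Abcb11, the bile salt export pump, fell (-0.70 ± 0.12, adjusted p = 0.000453). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass (1.18 ± 0.63), but did without LF library 5 (1.90). Among genes expressed more in male than in female liver, 0 of 23 genes rose, 9 fell and 14 did not pass (0 and 9 adjusted over the list alone). Its median was -0.55 (camera adjusted p = 0.00188, adjusted p = 0.937 with an estimated correlation). Elovl3, a fatty acid elongase, fell (-1.31 ± 0.31).

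In the acute phase and complement list, 0 of 27 genes rose, 22 fell and 5 did not pass (0 and 24 adjusted over the list alone). Its median was -1.12 (camera adjusted p = 8.85e-07, adjusted p = 0.754 with an estimated correlation). Fgg, the fibrinogen gamma chain, fell (-1.29 ± 0.18, adjusted p = 0.000152). The serum amyloid gene Saa2 (-4.35 ± 1.08), the neutrophil attractant Cxcl1 (-4.77 ± 0.92) and the metallothioneins Mt1 (-4.34 ± 0.97) and Mt2 (-5.63 ± 1.09, ENSMUSG00000031762, chromosome 8, 94172664 to 94173568) fell. Reads may be shared between Saa1 and Saa2 and between Mt1 and Mt2, which are close in sequence. The LF libraries were not alike in these genes. Mt2 stood at 385, 422, 354, 381, 2.04 and 0.892 CPM in LF libraries 1 to 6, against 5.15 ± 3.16 CPM in HF. Leaving out LF libraries 1 to 4 was an alternative chosen after seeing the data. In it the list median was 0.04 and camera pointed higher (adjusted p = 0.558), and Mt2, Cxcl1, Saa2 and Mt1 were higher in HF and did not pass (1.81, 0.75, 2.80 and 2.19).

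Genes of protein folding and stress fell together. In the unfolded protein and integrated stress response list, 1 of 29 genes rose, 22 fell and 6 did not pass (1 and 24 adjusted over the list alone). Its median was -0.56 (camera adjusted p = 8.85e-07, adjusted p = 0.717 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, fell (-1.11 ± 0.22, adjusted p = 0.00147), and so did the transcription factor Xbp1 (-1.07 ± 0.18). Among immediate early and heat shock genes, 0 of 20 genes rose, 17 fell and 3 did not pass (0 and 18 adjusted over the list alone). Its median was -1.18 (camera adjusted p = 5.16e-06, adjusted p = 0.717 with an estimated correlation). The chaperone Hspa8 (-0.95 ± 0.15) and the early response gene Junb (-2.17 ± 0.39), which overlaps Prdx2 on the other strand, fell. Junb stood at 407, 346, 207, 160, 67.5 and 72.3 CPM in LF libraries 1 to 6, and at 46.8 ± 16.1 CPM in HF. In the cytosolic ribosome list, 0 of 55 genes rose, 52 fell and 3 did not pass (0 and 54 adjusted over the list alone). Its median was -0.43 (camera adjusted p = 1.17e-20, adjusted p = 0.717 with an estimated correlation). Rplp0 (-0.48 ± 0.07) was among the falls.

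Among cell cycle genes, 12 of 22 genes rose, 0 fell and 10 did not pass (15 and 1 adjusted over the list alone). Its median was 0.89 (camera adjusted p = 0.000397, adjusted p = 0.717 with an estimated correlation). The proliferation marker Mki67 (1.5 ± 0.31) and the replication factor Mcm2 (1.08 ± 0.22) rose. In the microRNA processing list, 1 of 18 genes rose, 6 fell and 11 did not pass (1 and 6 adjusted over the list alone). Its median was -0.09 (camera adjusted p = 0.255). Ago2, which carries microRNAs in the silencing complex (-0.55 ± 0.11), and Khsrp, whose protein binds let-7 precursors (-0.39 ± 0.07), fell. Dicer1, which cuts microRNA precursors, did not pass (-0.14 ± 0.08), but did without HF library 5 (-0.20). In the let-7 target list, 1 of 28 genes rose, 11 fell and 16 did not pass (1 and 15 adjusted over the list alone). Its median was -0.34 (camera adjusted p = 0.00281, adjusted p = 0.724 with an estimated correlation). Irs2, which carries the insulin signal, fell (-1.67 ± 0.29, adjusted p = 0.000706). Without LF libraries 1 to 4 the list did not pass (adjusted p = 0.431).

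The largest rises in HF liver were those of Cfd, which encodes adipsin (4.44 ± 1.04), Sema5b (3.94 ± 0.47), Osbpl3 (3.64 ± 0.59), Raet1d (3.07 ± 0.42), Adgrv1 (2.88 ± 0.55) and Clstn3 (2.87 ± 0.39). Raet1d overlaps Raet1e on the same strand, so their reads may be shared. Adcy1, an adenylyl cyclase (-5.37 ± 0.70), Igfbp1, which binds insulin-like growth factors (-4.94 ± 0.87), and Fabp5, a fatty acid binding protein (-3.80 ± 0.57), fell. Of the clock genes, chosen after their values were seen, Dbp stood at 2.56 and 5.16 CPM in LF libraries 1 and 2. LF libraries 3 to 6 held 62.9 to 133, HF 131 to 182 and HFLF 88.2 to 170 CPM. Arntl stood at 5.52 to 17.1 CPM in LF, 2.75 to 5.39 in HF and 1.62 to 9.58 in HFLF. Ppargc1a, a regulator of mitochondrial biogenesis, did not pass (-0.30 ± 0.20). Limma voom ended the calls of Cfd (adjusted p = 0.0931) and Cidec (0.133), the replicate block those of Cidec (0.0728) and Saa2 (0.056), and the fit of only the 2 groups that of Scd1 (0.0759). Cfd stood at 1.39 and 1.49 CPM in HF libraries 5 and 6 and at 4.52 CPM in LF library 5. edgeR called 2742 genes without LF libraries 1 and 2 and 297 without LF libraries 1 to 4. The latter ended 33 of the 40 named calls, but not those of Sema5b, Adcy1, Cyp8b1, Abcb11, Hspa8, Irs2 and Fabp5.

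**Figure D1:**
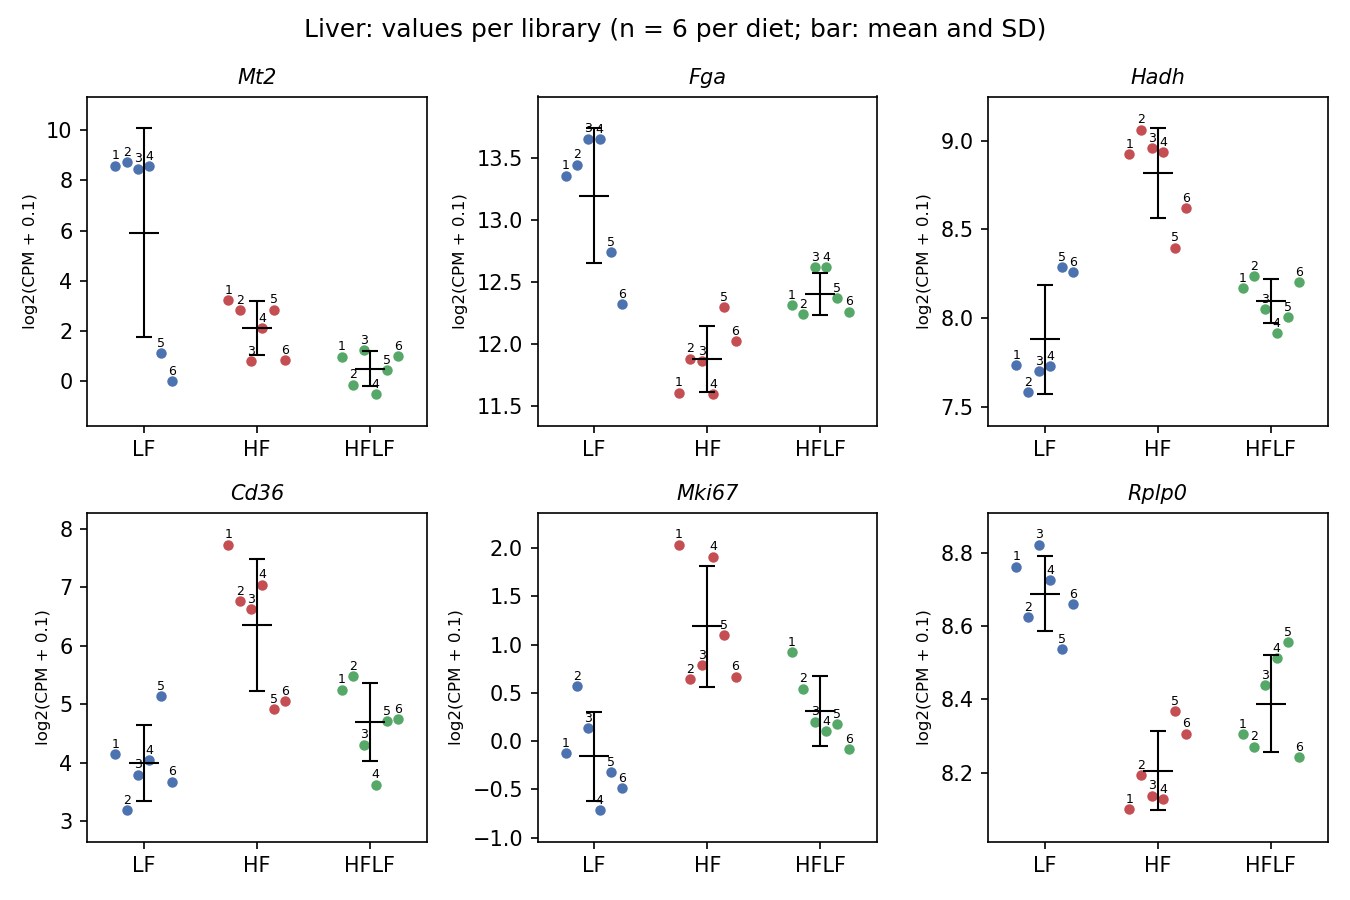
Levels of 6 liver genes on a log2(CPM + 0.1) axis, with a numbered point per library (n = 6 per diet) and black bars for mean and SD. Hadh and Cd36 were higher and Rplp0 lower in all 6 HF libraries than the LF mean.

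The comparison of HFLF with LF in liver asked what differed after the return to low-fat diet. Many acute-phase, stress and heat shock genes were lower in HFLF than in LF, and some fatty acid oxidation genes and B cell genes were higher. Hspa5 fell from 1495 ± 371 to 685 ± 206 CPM (-1.13 ± 0.22, adjusted p = 0.00264). Cpt1a, which brings fatty acids into mitochondria, rose from 454 ± 62.8 to 657 ± 69.2 CPM (0.53 ± 0.10, adjusted p = 0.00159). edgeR called 3176 of 14052 genes, 1432 higher and 1744 lower in HFLF (1866 and 1158 with upper-quartile factors). All 6 HFLF libraries lay on the side of the change for 28 of the 36 genes named, without overlap for 18.

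In the acute phase and complement list, 0 of 27 genes rose, 24 fell and 3 did not pass (0 and 25 adjusted over the list alone). Its median was -0.95 (camera adjusted p = 2.20e-10, adjusted p = 0.799 with an estimated correlation). Without LF libraries 1 to 4 that median was -0.09 (camera adjusted p = 0.204). The largest falls of the comparison were those of Saa2 (-7.24 ± 1.25), Saa1 (-6.30 ± 1.09), Mt2 (-7.48 ± 1.23), Mt1 (-5.87 ± 1.05), Cxcl1 (-6.03 ± 0.99) and Lcn2, an antibacterial protein that binds iron carriers (-5.84 ± 1.06). Crp fell too (-0.81 ± 0.12, adjusted p = 0.000719). Lcn2 stood at 50.5, 174, 305, 222, 3.23 and 1.28 CPM in LF libraries 1 to 6 and at 2.18 ± 0.915 CPM in HFLF. Without LF libraries 1 to 4, Mt1 was higher in HFLF and did not pass (0.65). In the unfolded protein and integrated stress response list, 0 of 29 genes rose, 21 fell and 8 did not pass (0 and 26 adjusted over the list alone). Its median was -0.76 (camera adjusted p = 2.51e-11, adjusted p = 0.474 with an estimated correlation). Dnajb11, a co-chaperone, fell (-0.89 ± 0.16). Among immediate early and heat shock genes, 0 of 20 genes rose, 18 fell and 2 did not pass (0 and 19 adjusted over the list alone). Its median was -1.46 (camera adjusted p = 6.68e-08, adjusted p = 0.799 with an estimated correlation). Junb (-2.04 ± 0.39) and the chaperone Hsph1 (-1.77 ± 0.29) fell.

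In the cytosolic ribosome list, 0 of 55 genes rose, 15 fell and 40 did not pass (0 and 27 adjusted over the list alone). Its median was -0.24 (camera adjusted p = 2.20e-10, adjusted p = 0.97 with an estimated correlation). Rplp0 fell (-0.30 ± 0.07). In the mitochondrial ribosome list, 0 of 54 genes rose, 13 fell and 41 did not pass (1 and 17 adjusted over the list alone). Its median was -0.11 (camera adjusted p = 0.00162, adjusted p = 0.909 with an estimated correlation). Mrps12 fell (-0.46 ± 0.06, adjusted p = 0.000388). In the fatty acid oxidation and PPARalpha target list, 8 of 35 genes rose, 0 fell and 27 did not pass (9 and 0 adjusted over the list alone). Its median was 0.28 (camera adjusted p = 8.68e-06, adjusted p = 0.909 with an estimated correlation). Ppara, the receptor that drives these genes, rose (0.76 ± 0.16, adjusted p = 0.00319). Without LF libraries 1 to 4 the list did not pass (adjusted p = 0.685). Fasn (0.12 ± 0.26), Scd1 (0.34 ± 0.37), Cd36 (0.68 ± 0.46) and Cidec (-0.16 ± 0.65) did not pass, and Fasn turned sign without HFLF library 3 (-0.03). Ppargc1a did not pass (-0.04 ± 0.20) and turned sign without LF libraries 1 or 5 (0.04 and 0.06) or HFLF libraries 2 or 4 (0.02 and 0.01). Cyp7a1 did not pass (1.13 ± 0.63), but did without LF library 5 (1.85).

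Among B and plasma cell markers, 8 of 13 genes rose, 0 fell and 5 did not pass (9 and 1 adjusted over the list alone). Its median was 1.27 (camera adjusted p = 0.0125, adjusted p = 0.859 with an estimated correlation). Mzb1, a protein of plasma cells, rose from 0.254 ± 0.0925 to 0.762 ± 0.299 CPM (1.56 ± 0.38, adjusted p = 0.0076). In the let-7 target list, 0 of 28 genes rose, 8 fell and 20 did not pass (1 and 8 adjusted over the list alone). Its median was -0.26 (camera adjusted p = 0.0805). Cdc34, a ubiquitin-conjugating enzyme, fell (-0.55 ± 0.09). The list passed without LF libraries 5 or 6 (0.0238 and 0.0299). Over the other alternatives its adjusted p was 0.0329 to 0.977. In the microRNA processing list, 2 of 18 genes rose, 1 fell and 15 did not pass (4 and 2 adjusted over the list alone). Its median was 0.06 (camera adjusted p = 0.727). Dicer1 did not pass (0.12 ± 0.08).

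The largest rises in HFLF liver were those of Dlec1 (4.12 ± 0.84), Pdzrn3 (2.22 ± 0.38), G0s2, an inhibitor of fat breakdown (1.94 ± 0.55), Rfx4 (1.92 ± 0.23), Osbpl3 (1.88 ± 0.60) and E2f8 (1.86 ± 0.46). Dlec1 overlaps Acaa1b, a peroxisomal oxidation gene, on the other strand. The counting strand is not given in the sources used here, so their reads cannot be told apart. The same holds for G0s2 with Lamb3. G0s2 did not pass without HFLF library 4 (1.19), and Osbpl3 did not pass without LF libraries 1, 2, 3 or 4 (1.84, 1.81, 1.85 and 1.88) or HFLF libraries 1, 5 or 6 (1.84, 1.75 and 1.89). Limma voom ended the calls of Osbpl3 (adjusted p = 0.136) and Mt2 (0.0506), and the fit of only the 2 groups that of G0s2 (0.0507). edgeR called 26 genes without LF libraries 1 to 4 and 1396 without LF libraries 1 and 2. Of the 29 named genes that passed, 24 no longer did without LF libraries 1 to 4.

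HFLF was next compared with HF in liver. Some genes of lipid droplets, fatty acid oxidation, the cell cycle and the mitochondrial ribosome were lower in HFLF than in HF, and some lipogenic genes were higher. Fabp5 rose from 9.44 ± 6.67 to 137 ± 67.5 CPM (3.86 ± 0.57, adjusted p = 0.00443, ENSMUSG00000027533, chromosome 3, 10012548 to 10016607). Lepr, the leptin receptor, rose from 2.39 ± 0.77 to 20.5 ± 6.1 CPM (3.08 ± 0.37, adjusted p = 0.00132, ENSMUSG00000057722, chromosome 4, 101717404 to 101815352). edgeR called 735 of 14052 genes, 307 higher and 428 lower in HFLF. All 6 HFLF libraries lay on the side of the change for 19 of the 22 genes named, without overlap for 12.

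In the lipid droplet and lipid uptake list, 0 of 25 genes rose, 8 fell and 17 did not pass (1 and 11 adjusted over the list alone). Its median was -0.20 (camera adjusted p = 0.0111, adjusted p = 0.706 with an estimated correlation). Cd36 fell (-1.87 ± 0.46, adjusted p = 0.0292), but did not pass without HF libraries 1, 2, 3 or 4 (-1.53, -1.86, -1.88 and -1.79) or HFLF libraries 3, 4, 5 or 6 (-1.79, -1.72, -1.86 and -1.86). Cidec fell (-2.33 ± 0.65, adjusted p = 0.0495), but did not pass without LF libraries 2, 3 or 4 (-2.33, -2.33 and -2.33), HF libraries 1, 2, 3 or 4 (-1.52, -2.54, -2.43 and -2.12) or HFLF libraries 1, 2, 3, 4, 5 or 6 (-2.31, -2.24, -2.27, -2.34, -2.37 and -2.46). In the fatty acid oxidation and PPARalpha target list, 0 of 35 genes rose, 6 fell and 29 did not pass (2 and 13 adjusted over the list alone). Its median was -0.25 (camera adjusted p = 5.50e-05, adjusted p = 0.706 with an estimated correlation). Hadh (-0.73 ± 0.13) and Acads, an acyl-CoA dehydrogenase (-0.41 ± 0.07), fell. Among de novo lipogenesis genes, 4 of 24 genes rose, 0 fell and 20 did not pass (6 and 0 adjusted over the list alone). Its median was 0.21 (camera adjusted p = 0.00995, adjusted p = 0.706 with an estimated correlation). The list did not pass without HF library 5 (0.103). Over the other alternatives its adjusted p was 0.00444 to 0.706. Scd1 rose (1.44 ± 0.37, adjusted p = 0.0355), but did not pass without HF libraries 2, 3 or 4 (1.32, 1.38 and 1.35) or HFLF libraries 1, 3, 5 or 6 (1.42, 1.40, 1.48 and 1.39). Pnpla3 rose (2.55 ± 0.57), but did not pass without HF libraries 3 or 4 (2.48 and 2.43). Fasn did not pass (0.48 ± 0.26).

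Among cell cycle genes, 0 of 22 genes rose, 5 fell and 17 did not pass (0 and 14 adjusted over the list alone). Its median was -0.89 (camera adjusted p = 1.34e-07, adjusted p = 0.263 with an estimated correlation). Mcm2 fell (-1.14 ± 0.22, adjusted p = 0.0101). In the mitochondrial ribosome list, 0 of 54 genes rose, 9 fell and 45 did not pass (0 and 17 adjusted over the list alone). Its median was -0.14 (camera adjusted p = 7.86e-09, adjusted p = 0.263 with an estimated correlation). Mrps27 fell (-0.35 ± 0.08). In the cytosolic ribosome list, 2 of 55 genes rose, 0 fell and 53 did not pass (17 and 0 adjusted over the list alone). Its median was 0.21 (camera adjusted p = 2.40e-12, adjusted p = 0.706 with an estimated correlation). Among antioxidant genes and targets of NRF2, 1 of 20 genes rose, 3 fell and 16 did not pass (1 and 9 adjusted over the list alone). Its median was -0.26 (camera adjusted p = 9.93e-06, adjusted p = 0.263 with an estimated correlation). Gpx1, a glutathione peroxidase, fell (-0.61 ± 0.09, adjusted p = 0.00432), and G6pdx, the first enzyme of the pentose phosphate pathway, rose (1.5 ± 0.29). In the microRNA processing list, 1 of 18 genes rose, 0 fell and 17 did not pass (4 and 0 adjusted over the list alone). Its median was 0.14 (camera adjusted p = 0.00117, adjusted p = 0.281 with an estimated correlation). Dicer1 did not pass (0.26 ± 0.08), but did without LF library 1 (0.26) or HF libraries 5 or 6 (0.31 and 0.29). In the let-7 target list, 1 of 28 genes rose, 0 fell and 27 did not pass (3 and 1 adjusted over the list alone). Its median was 0.16 (camera adjusted p = 0.0763).

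Adgrf1 rose (2.83 ± 0.56), while Cfd (-4.58 ± 1.07), Sema5b (-2.33 ± 0.42), Raet1d (-1.89 ± 0.39), the galectin Lgals1 (-2.14 ± 0.47) and the retinal dehydrogenase Aldh1a1 (-1.26 ± 0.27) fell. Cfd did not pass without HF library 4 (-3.64) or HFLF libraries 3, 4 or 6 (-4.37, -4.36 and -4.48), and Lgals1 did not pass without HF library 4 (-1.95) or HFLF library 6 (-2.03). Ppargc1a did not pass (0.25 ± 0.20). Cyp7a1 did not pass (-0.05 ± 0.62) and turned sign without HF libraries 2 or 6 (0.23 and 0.31) or HFLF libraries 2, 3, 4 or 5 (0.05, 0.02, 0.06 and 0.11). Limma voom ended the calls of Cfd (adjusted p = 0.0878) and Cidec (0.122), the replicate block those of Cidec (0.164) and Cd36 (0.0574), and the fit of only the 2 groups those of Cidec (0.0766) and Scd1 (0.0505). Dicer1 passed with DESeq2 (0.0267), limma voom (0.00988), a mean CPM of at least 5 (0.041) and only the 2 groups (0.0459). The number of genes called was 434 without HF 1, 264 without HF 2, 261 without HF 3, 215 without HF 4, 397 without HFLF 3, 391 without HFLF 4, 315 without HFLF 5 and 256 without HFLF 6. DESeq2 called 1312 genes, limma voom 1758, and edgeR with only the HFLF and HF libraries 1181. With the replicate block, 444 genes were called.

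The comparison of HF with LF in eWAT asked what the high-fat diet changed in adipose tissue. Many macrophage, extracellular matrix, cell cycle and antigen presentation genes rose in HF. Many genes of oxidative phosphorylation, the TCA cycle, lipogenesis and branched-chain amino acid breakdown fell. Trem2, a lipid receptor of macrophages, rose from 4.97 ± 1.12 to 229 ± 187 CPM (5.52 ± 0.71, adjusted p = 5.20e-05, ENSMUSG00000023992, chromosome 17, 48346401 to 48354147). Mmp12, the macrophage elastase, rose from 2.68 ± 0.606 to 688 ± 696 CPM (8.0 ± 0.91, adjusted p = 3.00e-05, ENSMUSG00000049723, chromosome 9, 7344381 to 7369499) and overlaps Mmp1b on the other strand. edgeR called 6817 of 16690 genes, 3441 higher and 3376 lower in HF (3051 and 3911 with upper-quartile factors). All 6 HF libraries lay on the side of the change for 43 of the 44 genes named, without overlap for 33.

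In the lipid-associated macrophage list, 17 of 20 genes rose, 1 fell and 2 did not pass (17 and 1 adjusted over the list alone). Its median was 2.18 (camera adjusted p = 2.28e-07, adjusted p = 0.505 with an estimated correlation). Gpnmb (6.47 ± 0.83), the proton pump subunit Atp6v0d2 (7.13 ± 0.83) and the integrin Itgax (5.34 ± 0.71) rose. Among macrophage markers, 14 of 19 genes rose, 0 fell and 5 did not pass (15 and 1 adjusted over the list alone). Its median was 1.67 (camera adjusted p = 2.85e-05, adjusted p = 0.505 with an estimated correlation). Adgre1, which encodes the F4/80 antigen, rose (3.14 ± 0.47, adjusted p = 0.000122), and so did Cd68 (3.62 ± 0.53). In the list of inflammatory cytokines and chemokines, 17 of 26 genes rose, 1 fell and 8 did not pass (18 and 1 adjusted over the list alone). Its median was 1.44 (camera adjusted p = 2.52e-05, adjusted p = 0.505 with an estimated correlation). Il1rn, the blocker of the interleukin-1 receptor (5.07 ± 0.64), and the chemokine receptor Ccr2 (1.64 ± 0.21) rose. Among antigen presentation genes, 14 of 16 genes rose, 0 fell and 2 did not pass (14 and 0 adjusted over the list alone). Its median was 0.81 (camera adjusted p = 1.80e-06, adjusted p = 0.505 with an estimated correlation). The MHC class II gene H2-Ab1 (1.24 ± 0.18) and its activator Ciita (2.08 ± 0.29) rose.

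In the fibrosis and extracellular matrix list, 27 of 32 genes rose, 1 fell and 4 did not pass (28 and 1 adjusted over the list alone). Its median was 1.32 (camera adjusted p = 6.93e-12, adjusted p = 0.505 with an estimated correlation). The collagen VI chains Col6a3 (1.81 ± 0.17, adjusted p = 1.81e-05) and Col6a1 (1.82 ± 0.20) rose. Among cell cycle genes, 26 of 27 genes rose, 0 fell and 1 did not pass (26 and 0 adjusted over the list alone). Its median was 2.17 (camera adjusted p = 7.38e-16, adjusted p = 0.505 with an estimated correlation). Mki67 (2.93 ± 0.29, adjusted p = 2.26e-05) and the mitotic kinase Cdk1 (2.99 ± 0.31) rose. Among endothelial markers, 1 of 17 genes rose, 1 fell and 15 did not pass (1 and 0 adjusted over the list alone). Its median was -0.13 (camera adjusted p = 0.461).

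In the list of nuclear oxidative phosphorylation genes, 0 of 76 genes rose, 66 fell and 10 did not pass (0 and 69 adjusted over the list alone). Its median was -0.44 (camera adjusted p = 3.19e-16, adjusted p = 0.505 with an estimated correlation). Ndufa5, a complex I subunit, fell (-0.80 ± 0.11, adjusted p = 7.53e-05), and so did Sdha, a complex II subunit (-0.76 ± 0.12). In the TCA cycle list, 0 of 25 genes rose, 20 fell and 5 did not pass (0 and 22 adjusted over the list alone). Its median was -0.52 (camera adjusted p = 1.37e-07, adjusted p = 0.505 with an estimated correlation). Suclg2 fell (-0.99 ± 0.14). In the list of mitochondrial biogenesis, dynamics and quality control, 0 of 34 genes rose, 15 fell and 19 did not pass (0 and 16 adjusted over the list alone). Its median was -0.24 (camera adjusted p = 0.000922, adjusted p = 0.505 with an estimated correlation). The mitochondrial protease Clpp (-0.90 ± 0.13) and Ppargc1a (-1.24 ± 0.35) fell. In the branched-chain amino acid breakdown list, 1 of 25 genes rose, 21 fell and 3 did not pass (1 and 23 adjusted over the list alone). Its median was -0.68 (camera adjusted p = 6.90e-08, adjusted p = 0.505 with an estimated correlation). Bcat2, the mitochondrial aminotransferase (-1.42 ± 0.26), and Hsd17b10 (-1.03 ± 0.16) fell.

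Among de novo lipogenesis genes, 0 of 24 genes rose, 19 fell and 5 did not pass (0 and 19 adjusted over the list alone). Its median was -1.16 (camera adjusted p = 2.28e-07, adjusted p = 0.505 with an estimated correlation). Acaca (-2.65 ± 0.35, adjusted p = 5.49e-05), Fasn (-1.65 ± 0.36) and Mlxipl, a transcription factor that responds to glucose (-1.29 ± 0.18), fell. Among adipocyte markers, 2 of 30 genes rose, 16 fell and 12 did not pass (2 and 16 adjusted over the list alone). Its median was -0.57 (camera adjusted p = 0.000922, adjusted p = 0.643 with an estimated correlation). Cfd fell from 11519 ± 4824 to 760.3 ± 549.9 CPM (-3.92 ± 0.54, adjusted p = 7.45e-05) and Pnpla2, the first lipase of fat breakdown, fell (-1.15 ± 0.21). Adipoq, which encodes adiponectin, fell (-0.82 ± 0.28, adjusted p = 0.0243), but did not pass without HF libraries 1 or 4 (-0.72 and -0.72). Lep, which encodes leptin, rose from 943 ± 720.2 to 3619.5 ± 797 CPM (1.94 ± 0.42, adjusted p = 0.00177, ENSMUSG00000059201, chromosome 6, 29060220 to 29073877), and Mest, an imprinted gene of fat expansion, rose (2.34 ± 0.47).

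In the microRNA processing list, 5 of 18 genes rose, 0 fell and 13 did not pass (4 and 0 adjusted over the list alone). Its median was 0.09 (camera adjusted p = 0.276). Ago2 rose (0.56 ± 0.09). Dicer1 did not pass (-0.15 ± 0.07), but did without HF library 4 (-0.18). In the let-7 target list, 10 of 30 genes rose, 5 fell and 15 did not pass (11 and 6 adjusted over the list alone). Its median was 0.12 (camera adjusted p = 0.458). Nras (0.72 ± 0.10) and the chromatin protein gene Hmga1 (2.04 ± 0.41) rose.

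The largest rises besides Mmp12 and Atp6v0d2 were those of Tm4sf19 (7.69 ± 1.08), Vsig8 (7.12 ± 0.78), Gpr50 (6.71 ± 1.03) and Gdf3 (6.57 ± 0.77). The counts of Tm4sf19 over the 6 LF libraries came to 9. The largest falls were those of Akr1b7 (-8.43 ± 2.31, adjusted p = 0.00813), Ppp1r1b (-7.16 ± 1.88), Kcnk1 (-6.61 ± 1.90), Clic6 (-6.53 ± 1.28), Prom2 (-6.32 ± 2.14) and Hnf4a (-5.86 ± 1.78). Akr1b7 stood at 842 CPM in LF library 3 and at 0.394 ± 0.335 CPM in HF. Akr1b7 did not pass without LF library 3 (-0.06), and Prom2 did not pass without LF library 4 (-5.28) or HF libraries 3 or 4 (-6.11 and -6.04). With limma voom on all libraries Akr1b7 stood at 0.10, and Ppp1r1b (-2.94), Kcnk1 (-2.79), Prom2 (-2.30) and Hnf4a (-2.08) did not pass. Adipoq did not pass in the fit of only the 2 groups (adjusted p = 0.0605), and Dicer1 did with upper-quartile factors (0.0257). With the replicate block Akr1b7 (-3.98), Prom2 (-4.14) and Hnf4a (-3.39) did not pass. LF library 3 also held 218 CPM of Crisp1, an epididymal gene, and 638 CPM of Cnn1, a smooth muscle gene. HF library 1 held 333 CPM and LF library 4 124 CPM of the sperm gene Prm2. Crisp1, Cnn1 and Prm2 were chosen after their values were seen. Genes of other tissues stood out in LF libraries 3, 4 and 5, HF library 1 and HFLF libraries 4 and 6. With these 6 set aside, edgeR called 5203 genes. LF library 2, kept, also held 35.8 CPM of Prm2 and 30.4 CPM of Cnn1.

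**Figure D2:**
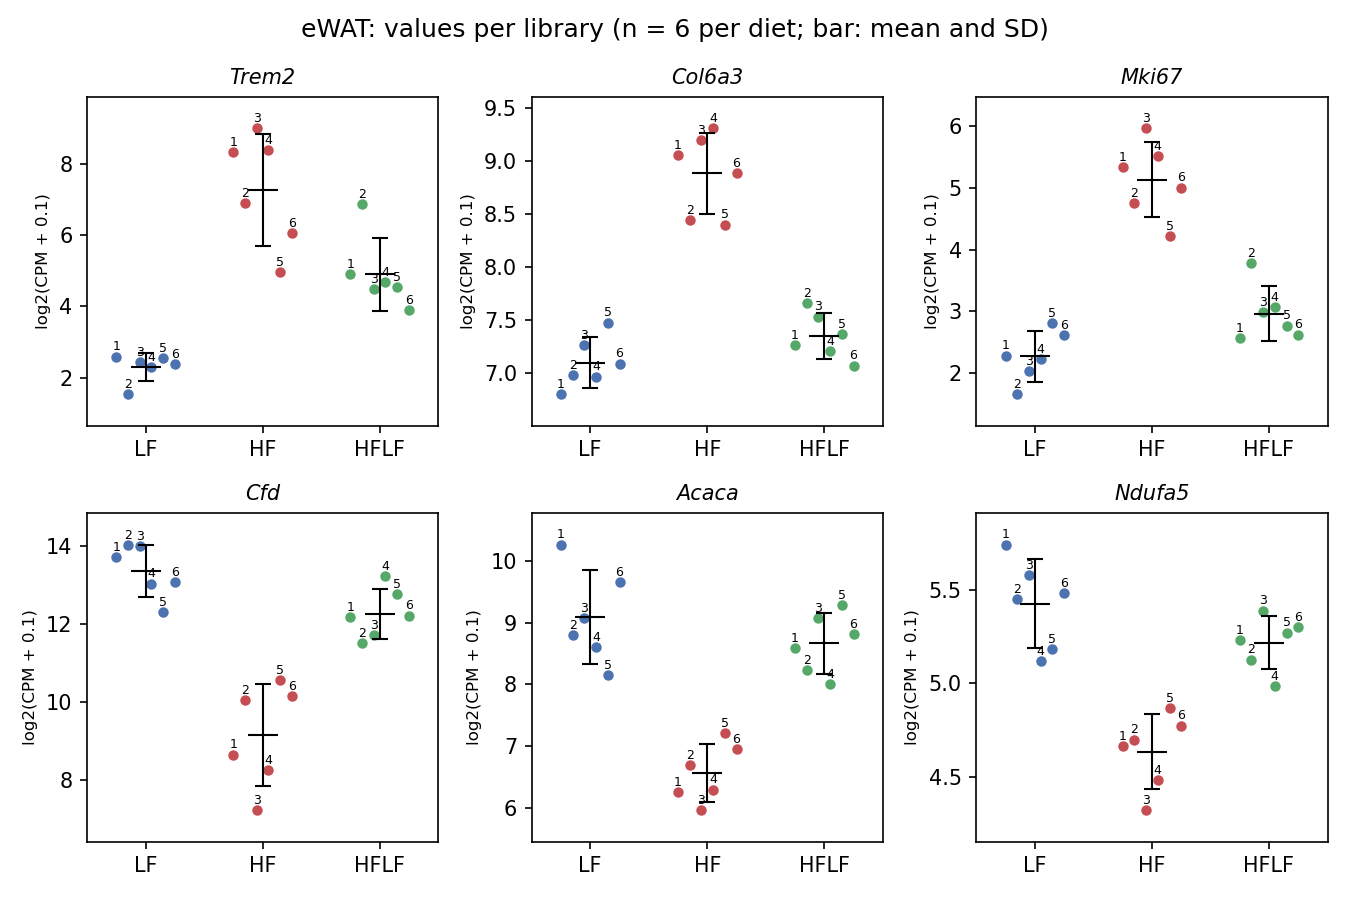
Levels of 6 eWAT genes on a log2(CPM + 0.1) axis, with a numbered point per library (n = 6 per diet) and black bars for mean and SD. Trem2 ranged from 2.83 to 5.93 CPM in LF, from 31.3 to 508 CPM in HF and from 14.8 to 116 CPM in HFLF.

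**Figure D3:**
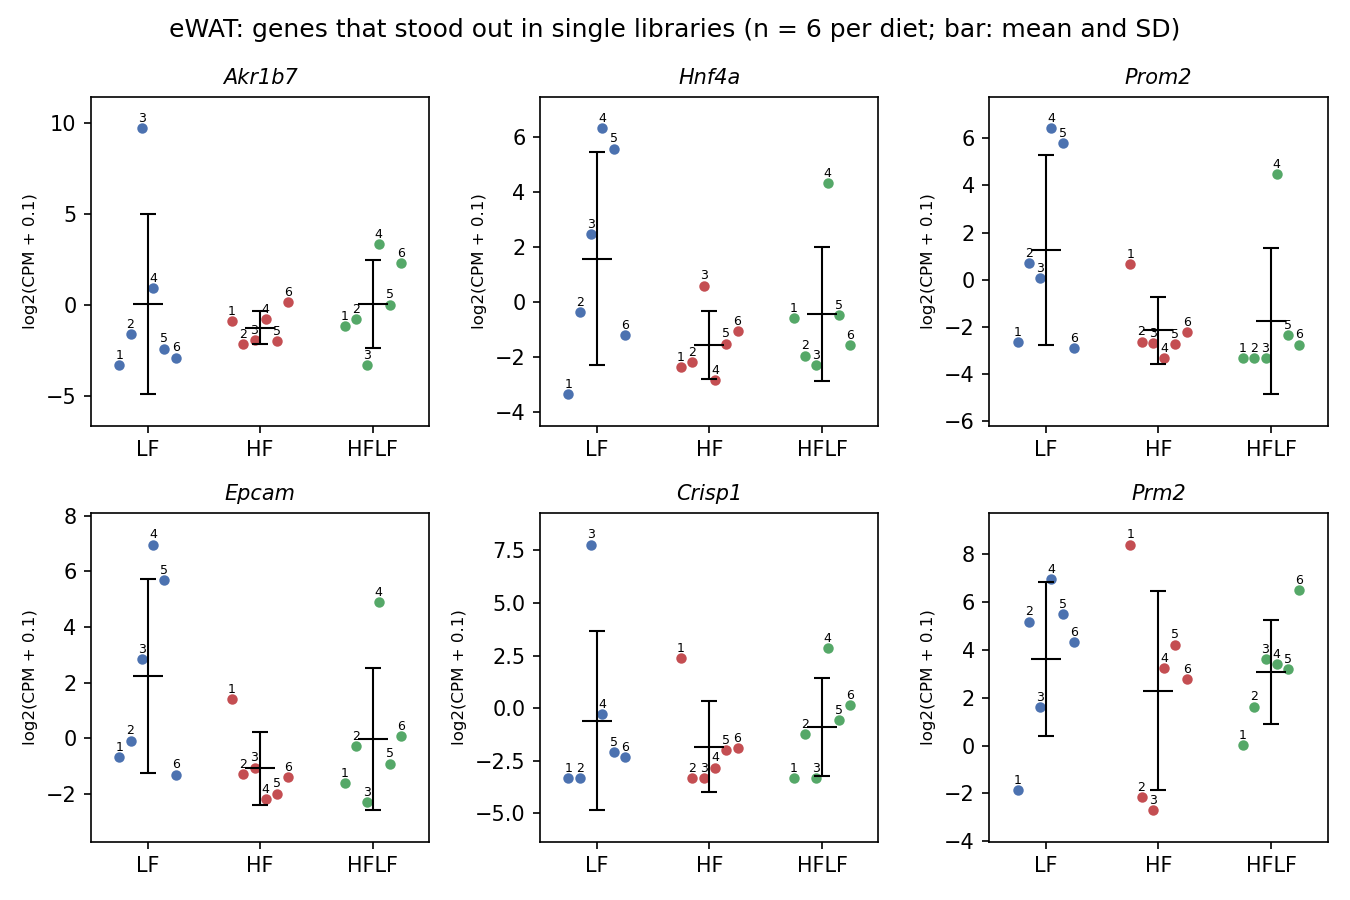
Levels of 6 genes that stood out in single eWAT libraries, on a log2(CPM + 0.1) axis, with a numbered point per library (n = 6 per diet) and black bars for mean and SD.

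The comparison of HFLF with LF in eWAT asked what differed after the return to low-fat diet. In HFLF, 4 of 20 lipid-associated macrophage genes were higher than in LF, and of each other list at most 1 gene passed. Mmp12 rose from 2.68 ± 0.606 to 212 ± 260 CPM (6.30 ± 0.86, adjusted p = 0.0178) and Gpnmb from 18.6 ± 6.15 to 225 ± 248 CPM (3.60 ± 0.73). HFLF library 2 stood apart, with 738 CPM of Mmp12 against 59.3 to 158 CPM in the other HFLF libraries. Without it Mmp12 still passed (5.31), while Gpnmb (2.75), Atp6v0d2 (3.46) and Itgax (2.34) did not. edgeR called 94 of 16690 genes, 57 higher and 37 lower, and 3028 genes had an unadjusted p under 0.05. All 6 HFLF libraries lay on the side of the change for 23 of the 28 genes named, without overlap for 17.

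In the lipid-associated macrophage list, 4 of 20 genes rose, 0 fell and 16 did not pass (8 and 0 adjusted over the list alone). Its median was 0.48 (camera adjusted p = 2.81e-07, adjusted p = 0.713 with an estimated correlation). Atp6v0d2 (4.27 ± 0.77) and Itgax (3.11 ± 0.65) rose. Trem2 did not pass (2.94 ± 0.65, adjusted p = 0.0515), but did without LF library 5 (2.99), HF libraries 3 or 5 (2.94 and 2.94) or HFLF library 4 (3.03), with DESeq2 (adjusted p = 9.82e-05) and in 4 other edgeR fits (0.0414 to 0.0486). Among T and NK cell markers, 1 of 22 genes rose, 0 fell and 21 did not pass (7 and 0 adjusted over the list alone). Its median was 0.90 (camera adjusted p = 2.65e-06, adjusted p = 0.713 with an estimated correlation). Gzma, a granzyme of cytotoxic cells, rose from 0.492 ± 0.19 to 1.4 ± 0.441 CPM (1.48 ± 0.30). Among interferon response genes, 1 of 25 genes rose, 0 fell and 24 did not pass (2 and 0 adjusted over the list alone). Its median was 0.30 (camera adjusted p = 2.81e-07, adjusted p = 0.713 with an estimated correlation). Ifih1, a sensor of viral RNA, rose (0.37 ± 0.08). Among immediate early and heat shock genes, 0 of 23 genes rose, 0 fell and 23 did not pass (0 and 10 adjusted over the list alone). Its median was -0.42 (camera adjusted p = 6.29e-05, adjusted p = 0.713 with an estimated correlation). There edgeR gave 12 members an unadjusted p under 0.05, DESeq2 called 6 and limma voom 5. Hspa1a, nearly identical to Hspa1b, did not pass (-1.01 ± 0.23), but did without LF library 5 (-1.11) or HF library 5 (-1.01), with DESeq2 (adjusted p = 0.00299) and with limma voom (0.0136). Among de novo lipogenesis genes, 0 of 24 genes rose, 1 fell and 23 did not pass (0 and 6 adjusted over the list alone). Its median was -0.31 (camera adjusted p = 9.39e-05, adjusted p = 0.713 with an estimated correlation). Fads1, a fatty acid desaturase, fell (-0.93 ± 0.18). In the list of nuclear oxidative phosphorylation genes, 0 of 76 genes rose, 0 fell and 76 did not pass (0 and 0 adjusted over the list alone). Its median was -0.15 (camera adjusted p = 6.19e-07, adjusted p = 0.713 with an estimated correlation). There edgeR gave 9 members an unadjusted p under 0.05, DESeq2 called 0 and limma voom 1.

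In the microRNA processing list, 0 of 18 genes rose, 0 fell and 18 did not pass (2 and 0 adjusted over the list alone). Its median was 0.05 (camera adjusted p = 0.18). There edgeR gave 4 members an unadjusted p under 0.05, DESeq2 called 0 and limma voom 3. In the let-7 target list, 0 of 30 genes rose, 0 fell and 30 did not pass (0 and 0 adjusted over the list alone). Its median was 0.01 (camera adjusted p = 0.84). There edgeR gave 2 members an unadjusted p under 0.05, DESeq2 called 0 and limma voom 0. The list mean was -0.07, unlike the median in sign. Camera pointed higher, but lower without HFLF library 4 (adjusted p = 0.924) or the 6 libraries set aside (0.737). Lep (0.49 ± 0.41), Adipoq (0.12 ± 0.27), Fasn (-0.14 ± 0.35), Ppargc1a (-0.52 ± 0.35) and Dicer1 (-0.02 ± 0.07) did not pass. Fasn turned sign without LF library 1 (0.17) or HFLF library 4 (0.02), and Dicer1 without HFLF library 1 (0.01). Mest did not pass (0.88 ± 0.45), but did without LF library 5 (1.49) or with limma voom (adjusted p = 0.048).

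The largest rises besides those above were those of Rgs1 (3.81 ± 0.82), Vsig8 (3.58 ± 0.75) and Gdf3 (3.52 ± 0.72). The largest falls were those of Tmem252 (-1.82 ± 0.37), Dok7 (-1.55 ± 0.33), Chchd10, a mitochondrial protein gene (-1.42 ± 0.28), Tst (-1.40 ± 0.31), Fkbp5, a target of the glucocorticoid receptor (-1.23 ± 0.26), and Sesn2, a stress sensor (-1.23 ± 0.20). Each gene that passed here did not pass without at least 1 library. The number of genes called was 0 without LF 1, 2 or 4, 4 without LF 3, 341 without LF 5, 37 without HF 1, 56 without HF 4, 38 without HF 6, 1 without HFLF 1, 2, 3, 5 or 6 and 173 without HFLF 4. DESeq2 called 704 genes, limma voom 679, edgeR with only the HFLF and LF libraries 50, and edgeR with the replicate block 15. Of the 20 named genes that passed, limma voom ended 5 calls, the fit of only the 2 groups 8 and the replicate block 14. Without the 6 eWAT libraries set aside, edgeR called 6 genes and none of these 20.

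HFLF was next compared with HF in eWAT. Many cell cycle, extracellular matrix and macrophage genes fell, and some genes of oxidative phosphorylation, lipogenesis and branched-chain amino acid breakdown rose. Col6a3 fell from 484 ± 122 to 165 ± 25.1 CPM (-1.56 ± 0.16, adjusted p = 0.000238), and Acaca rose from 98.4 ± 32.5 to 426 ± 140.5 CPM (2.12 ± 0.34, adjusted p = 0.00101). edgeR called 4242 of 16690 genes, 1784 higher and 2458 lower in HFLF (2352 and 2033 with upper-quartile factors). All 6 HFLF libraries lay on the side of the change for 34 of the 36 genes named, without overlap for 21.

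Among cell cycle genes, 0 of 27 genes rose, 26 fell and 1 did not pass (0 and 26 adjusted over the list alone). Its median was -1.87 (camera adjusted p = 3.55e-18, adjusted p = 0.601 with an estimated correlation). Mki67 (-2.23 ± 0.28) and the cyclin gene Ccna2 (-2.29 ± 0.29) fell. In the fibrosis and extracellular matrix list, 0 of 32 genes rose, 24 fell and 8 did not pass (0 and 26 adjusted over the list alone). Its median was -1.23 (camera adjusted p = 2.42e-12, adjusted p = 0.601 with an estimated correlation). The collagen gene Col3a1 (-1.82 ± 0.26) and Timp1, an inhibitor of matrix proteases (-3.90 ± 0.64), fell.

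In the lipid-associated macrophage list, 1 of 20 genes rose, 12 fell and 7 did not pass (1 and 17 adjusted over the list alone). Its median was -1.5 (camera adjusted p = 3.68e-05, adjusted p = 0.601 with an estimated correlation). Trem2 (-2.58 ± 0.61, adjusted p = 0.00658), Gpnmb (-2.87 ± 0.70), Itgax (-2.22 ± 0.60) and the galectin Lgals3 (-2.08 ± 0.45) fell, while Apoe, which carries lipids, rose (0.61 ± 0.10). Mmp12 did not pass (-1.70 ± 0.67), but did without HF libraries 5 or 6 (-1.93 and -1.91) or HFLF library 2 (-2.69) or with DESeq2 (adjusted p = 0.036). Among macrophage markers, 0 of 19 genes rose, 13 fell and 6 did not pass (0 and 14 adjusted over the list alone). Its median was -1.23 (camera adjusted p = 0.000406, adjusted p = 0.619 with an estimated correlation). Adgre1 (-2.18 ± 0.45) and the complement gene C1qb (-1.49 ± 0.32) fell. In the list of inflammatory cytokines and chemokines, 0 of 26 genes rose, 12 fell and 14 did not pass (0 and 14 adjusted over the list alone). Its median was -0.95 (camera adjusted p = 7.25e-05, adjusted p = 0.601 with an estimated correlation). Il1rn (-3.39 ± 0.57) and the monocyte attractant Ccl2 (-2.70 ± 0.52) fell.

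In the list of nuclear oxidative phosphorylation genes, 36 of 76 genes rose, 0 fell and 40 did not pass (56 and 0 adjusted over the list alone). Its median was 0.33 (camera adjusted p = 2.09e-13, adjusted p = 0.619 with an estimated correlation). Ndufa5 rose (0.58 ± 0.11). In the branched-chain amino acid breakdown list, 16 of 25 genes rose, 0 fell and 9 did not pass (22 and 1 adjusted over the list alone). Its median was 0.60 (camera adjusted p = 2.01e-08, adjusted p = 0.601 with an estimated correlation). The phosphatase Ppm1k (0.98 ± 0.12) and Ivd, which breaks down leucine (1.07 ± 0.25), rose. Among de novo lipogenesis genes, 10 of 24 genes rose, 0 fell and 14 did not pass (12 and 0 adjusted over the list alone). Its median was 0.59 (camera adjusted p = 3.26e-05, adjusted p = 0.601 with an estimated correlation). Fasn (1.52 ± 0.36, adjusted p = 0.00618) and the elongase Elovl6 (1.93 ± 0.37) rose. Among adipocyte markers, 13 of 30 genes rose, 2 fell and 15 did not pass (15 and 2 adjusted over the list alone). Its median was 0.50 (camera adjusted p = 0.00037, adjusted p = 0.709 with an estimated correlation). Cfd rose from 760.3 ± 549.9 to 5385 ± 2517 CPM (2.82 ± 0.51, adjusted p = 0.00182), and Adipoq rose (0.94 ± 0.28). Lep fell (-1.45 ± 0.42, adjusted p = 0.0179), and Mest fell (-1.46 ± 0.45), but Mest did not pass without HFLF libraries 4, 5 or 6 (-1.35, -1.36 and -1.39). In the let-7 target list, 3 of 30 genes rose, 7 fell and 20 did not pass (4 and 8 adjusted over the list alone). Its median was -0.20 (camera adjusted p = 0.446). In the microRNA processing list, 1 of 18 genes rose, 1 fell and 16 did not pass (1 and 1 adjusted over the list alone). Its median was -0.09 (camera adjusted p = 0.599). Neither Dicer1 (0.12 ± 0.07) nor Ppargc1a (0.72 ± 0.35) passed without a block, but Ppargc1a did with the replicate block (adjusted p = 0.0436).

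Among the largest rises were those of Clic6 (4.54 ± 1.21), Fam13a (2.90 ± 0.43), Cfd, Cyp2f2 (2.76 ± 0.69) and Acsm3 (2.75 ± 0.66). Clic6 did not pass without HFLF library 4 (2.67) or with limma voom (2.97, adjusted p = 0.127), nor did Cyp2f2 with limma voom (2.35, adjusted p = 0.19). Mest did not pass with the replicate block (adjusted p = 0.0641). Besides Timp1, the largest falls were those of the integrin Itgad (-5.86 ± 0.93), Tph2 (-4.06 ± 0.61), the ubiquitin-like Ubd (-3.97 ± 0.44), Tm4sf19 (-3.64 ± 0.83) and Vsig8 (-3.53 ± 0.62). Without the 6 eWAT libraries set aside, edgeR called 1390 genes, and 12 of the 33 named genes that passed no longer did.

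**Figure D4:**
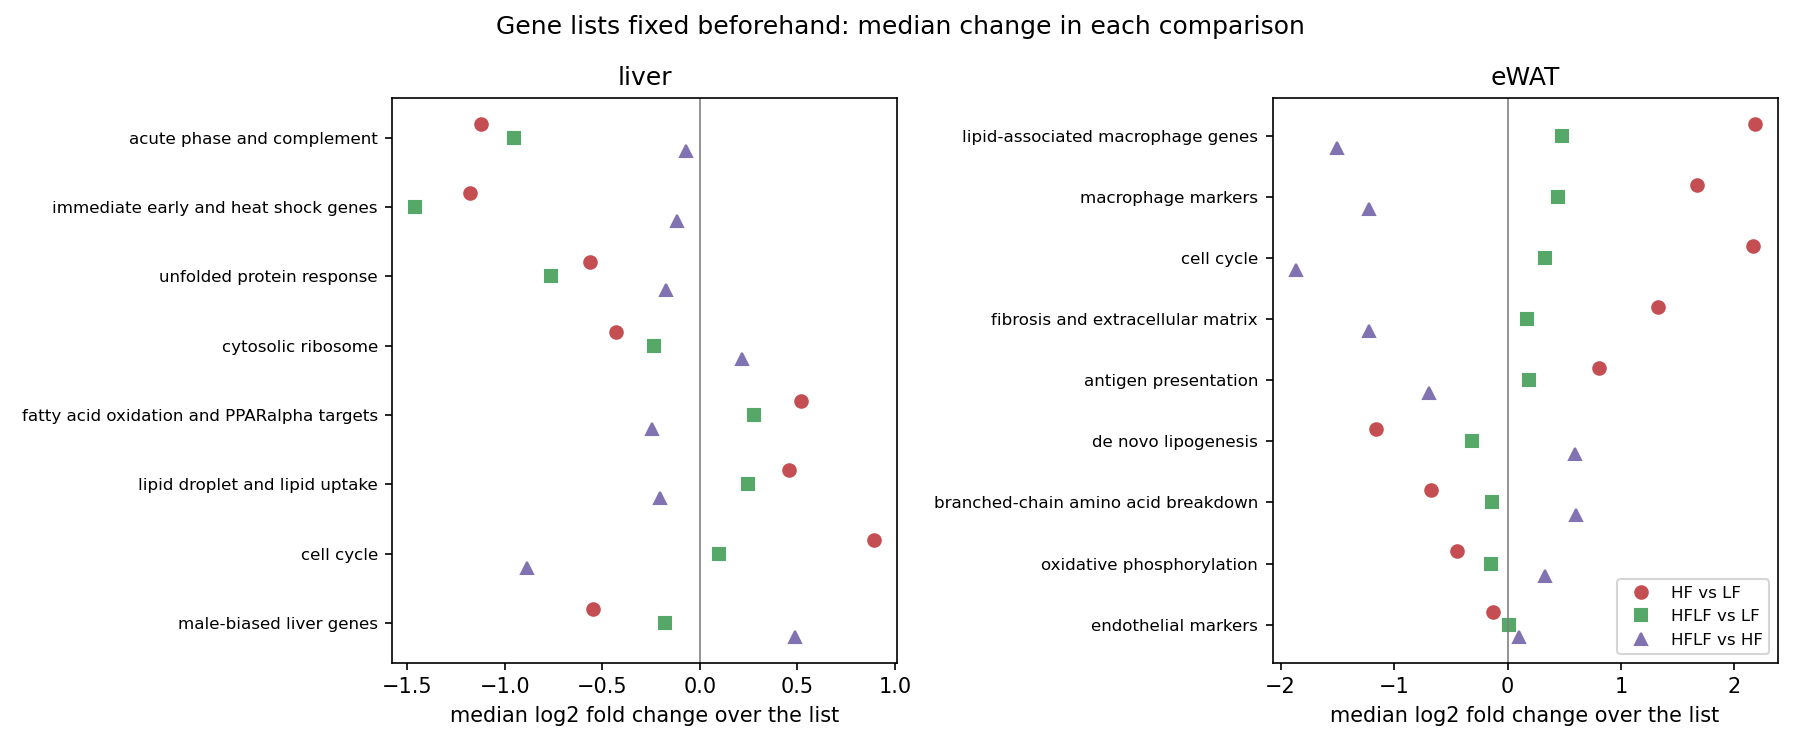
Median log2 fold change over the measured genes of each list (horizontal axis), for 8 lists in liver and 9 in eWAT, with one mark per comparison.

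To ask which changes of the HF diet were also present in HFLF, the genes called in both comparisons with LF were counted. In liver, 2177 genes passed in both with the same direction, 942 higher and 1235 lower, and 5 passed in opposite directions. They made up 44.5% of the HF calls and 68.5% of the HFLF calls. The product of the list sizes over the genes tested was 233.9 for higher and 322.2 for lower genes. In eWAT, 85 genes passed in both, 51 higher and 34 lower, which made up 90.4% of the HFLF calls, with products of 11.8 and 7.5. In 20 simulations of unchanged groups with shared LF libraries, the overlap was 0 in both tissues. At an unadjusted p under 0.05 its median was 132.5 in liver and 166.5 in eWAT, against 3580 and 2154 observed. No state shared by some LF libraries was simulated, so overlap due to one was not tested. With 3 of the 6 LF libraries per comparison, the median overlap was 731 genes in liver (262 to 958, 20 splits) and 0.5 in eWAT (0 to 352).

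The liver genes with the strongest calls in both comparisons were Extl1 (1.55 ± 0.15, adjusted p = 6.69e-05, ENSMUSG00000028838, chromosome 4, 134356372 to 134383850), Rasgef1b (-1.16 ± 0.13), Miga2, a gene of mitochondrial fusion (1.20 ± 0.14), Efna5 (1.28 ± 0.15), Nmnat3, of mitochondrial NAD synthesis (1.11 ± 0.14), and Lipe, the hormone-sensitive lipase (0.80 ± 0.10), given for HFLF against LF. The overlap was 20 of 297 HF calls without LF libraries 1 to 4, 819 without LF libraries 1 and 2, and 1375 without LF library 2.

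In eWAT these genes were Mmp12 (6.30 ± 0.86), Pde7a, a cyclic AMP phosphodiesterase (0.99 ± 0.16), Crybg3 (0.36 ± 0.06), Tmeff2 (0.90 ± 0.16), Tmem273 (0.60 ± 0.11) and Atp6v0d2 (4.27 ± 0.77). The eWAT overlap was 0 to 309 over the fits without 1 library. DESeq2 gave an overlap of 561 genes, the replicate block 13, and the fit without the 6 eWAT libraries set aside gave 6.

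HF calls that turned back were those called in the opposite direction in HFLF against HF. In liver, 478 genes (9.8% of the HF calls) turned back, 288 higher and then lower and 190 lower and then higher, against products of 69.9 and 56.7. In eWAT, 3620 genes (53.1% of the HF calls) turned back, 2120 higher and then lower and 1500 lower and then higher, against products of 506.8 and 360.9. These products leave out that both comparisons share the HF libraries. In 20 simulations of unchanged groups with shared HF libraries, 0 genes turned back, and at an unadjusted p under 0.05 a median of 140.5 in liver and 169 in eWAT, against 1829 and 5168 observed. In liver 8 and in eWAT 0 genes moved further in the HF direction. With 3 of the 6 HF libraries per comparison, the median was 33.5 genes in liver (1 to 255, 20 splits) and 1704 in eWAT (421 to 2305). The liver count was 150 to 690 without 1 library. Without LF libraries 1 to 4 it was 136 of 297 HF calls, so the 9.8% depends on these libraries. The eWAT count was 2664 to 4511 without 1 library, and 1190 of 5203 without the 6 libraries set aside.

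To ask whether the diets acted differently in the tissues, the difference of the effects was tested over the 13206 genes in both tables. The HF effect against LF differed between tissues for 6019 genes, 2776 with a higher log2 fold change in eWAT and 3243 with a lower one. Of the genes called in both tissues, 1090 changed in opposite directions, each with a difference that passed, and 841 in the same direction. The largest positive differences, eWAT minus liver, were those of the retinol dehydrogenase gene Dhrs9 (8.11 ± 0.96), Rgs1 (7.51 ± 1.01), Il1rn (7.12 ± 0.91) and the serum amyloid gene Saa3 (6.97 ± 0.89). The largest negative ones were those of Cfd (-8.40 ± 1.21), Ppp1r1b (-7.56 ± 1.70), Myo15b (-6.29 ± 1.87) and Wnk2 (-6.27 ± 1.39). With limma voom and the number as a block across tissues, Myo15b (-2.19, adjusted p = 0.351) and Wnk2 (-4.32, adjusted p = 0.0837) did not pass, nor did they with limma voom alone (0.366 and 0.0913).

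The HFLF effect against LF differed between tissues for 1130 genes, 475 with a higher log2 fold change in eWAT and 655 with a lower one. Called in both tissues were 20 genes in the same direction and 0 in opposite directions. The largest differences were those of Mmp12 (6.52 ± 1.31), Mt2 (6.39 ± 1.17), Cxcl1 (5.25 ± 1.08) and the acute-phase gene Orm2 (5.17 ± 0.93). On the negative side stood Dlec1 (-5.54 ± 1.07), Rbfox3 (-4.97 ± 1.29), Vwce (-3.47 ± 0.72) and Hcn3 (-3.23 ± 0.93), which overlaps Pklr, a glycolytic gene, on the other strand. With limma voom and that block Dlec1 and Vwce passed, but not Mmp12 (adjusted p = 0.0502), Mt2 (0.242), Cxcl1 (0.265), Orm2 (0.14), Rbfox3 (0.214) or Hcn3 (0.164), and the same held without the block. Without the liver LF libraries 1 to 4 and the 6 eWAT libraries set aside, 2502 genes differed for HF and 14 for HFLF. Myo15b, Mt2 and Cxcl1 then turned sign (1.18, -1.53 and -1.08).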

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

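The tests of explanations and the other splits of the samples in this part were chosen after the results were seen. The tests of the difference between tissues were set before.

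A library was taken as far from the others of its tissue and diet when its gap to the nearest of them, as a share of the range of all 6, passed Dixon's critical ratio. That held in 40 of 546 groups of 6 libraries, 1 group per gene or list, and chance gives about 1 in 20. The share is given for each. In liver, LF library 1 was highest for the mean of the cytosolic ribosome list (0.702) and lowest for G0s2 (0.686). LF library 4 was highest for Mcm2 (0.663) and lowest for the mean of the de novo lipogenesis list (0.646). LF library 5 was highest for Cfd (0.709), Sema5b (0.658), Fitm1 (0.736), Pdzrn3 (0.654) and E2f8 (0.695). In liver, HF library 1 was lowest for Mrps12 (0.68). HF library 5 was highest for the mean of the acute phase and complement list (0.632) and lowest for Cyp8b1 (0.636). In liver, HFLF library 3 was highest for Cxcl1 (0.736) and lowest for Dicer1 (0.645). HFLF library 4 was lowest for the mean of the de novo lipogenesis list (0.654) and Rasgef1b (0.793). HFLF library 5 was lowest for Mzb1 (0.691). HFLF library 6 was highest for Cpt1a (0.644) and lowest for Junb (0.627). In eWAT, LF library 2 was lowest for Trem2 (0.723). LF library 3 was highest for Akr1b7 (0.675). LF library 4 was lowest for Ifih1 (0.677) and Tmeff2 (0.689). In eWAT, HF library 1 was highest for Prom2 (0.728). HF library 5 was lowest for Ubd (0.693). In eWAT, HFLF library 2 was highest for the mean of the cell cycle list (0.638), the mean of the lipid-associated macrophage list (0.635), Tm4sf19 (0.759), Vsig8 (0.774), Trem2 (0.658), Gpnmb (0.716), Adgre1 (0.725), Cd68 (0.626), C1qb (0.651) and Lgals3 (0.848). HFLF library 4 was highest for Ppp1r1b (0.793), Kcnk1 (0.728), Clic6 (0.777), Prom2 (0.876) and Hnf4a (0.725).

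The diet effect differed between tissues for 6019 genes in HF against LF and for 1130 in HFLF against LF. Among the named genes the difference in HF, eWAT minus liver, was 8.11 for Dhrs9, 7.51 for Rgs1, 7.12 for Il1rn and 6.97 for Saa3, and it was -8.40 for Cfd, -7.56 for Ppp1r1b, -6.29 for Myo15b and -6.27 for Wnk2. In HFLF it was 6.52 for Mmp12, 6.39 for Mt2, 5.25 for Cxcl1 and 5.17 for Orm2, and it was -5.54 for Dlec1, -4.97 for Rbfox3, -3.47 for Vwce and -3.23 for Hcn3. With limma voom, with or without the number as a block, 2 of these 8 for HF and 6 of these 8 for HFLF did not pass.

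Acute-phase genes were lower in liver of HF and HFLF than of LF. Under upper-quartile factors the list median for HF against LF was -1.05 (-1.12 with TMM). These factors moved the median of all genes only from 0 to 0.07, so this test could not decide on scaling as the cause. The list mean lay above every HF and HFLF library (highest 8.41 log2 CPM) in 4 LF libraries (9.29, 9.7, 10.09 and 10 in LF libraries 1 to 4), and at 7.81 and 7.49 in LF libraries 5 and 6, consistent with an acute-phase state of part of the LF libraries. With LF libraries 1 to 4 left out, edgeR called 0 of 27 genes lower and 1 higher in HF (5 and 9 at an unadjusted p under 0.05). The median was 0.04 for HF and -0.09 for HFLF. With only 2 LF libraries left, an effect of the diet cannot be told apart from none.

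Among the largest falls in eWAT of HF, Akr1b7, Ppp1r1b, Kcnk1, Prom2 and Hnf4a stood at 2.34, -1.75, -2.22, -3.03 and 0.42 without the 6 libraries with genes of other tissues, and 1 of the 5, Ppp1r1b, was still called (edgeR, 2 at an unadjusted p under 0.05). These libraries were chosen because such genes stood out in them, so that the lost calls decide nothing, and with limma voom on all libraries Ppp1r1b did not pass (-2.94). For these 5 genes, other tissue carried into LF libraries 3, 4 and 5 cannot be told apart from other causes. Without LF library 3, Akr1b7 stood at -0.06 (SE 1.25), and 1 of the other 5 LF libraries lay above every HF library, which argues against a diet effect shared by the LF libraries. Clic6 was still called (-3.78) without the 6 libraries, and LF libraries 1, 2 and 6 (2.115, 6.51 and 2.704 CPM) lay above every HF library. This argues against other tissue in LF libraries 3, 4 and 5 as its whole cause. How these tests are read was changed after the results were seen.

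Macrophage genes were higher and adipocyte and oxidative phosphorylation genes lower in eWAT of HF than of LF. A lower share of adipocytes alone would raise the markers of other cells alike, but the macrophage mean rose by 1.59 (SE 0.49) more than the endothelial mean (1.54 and -0.05 on the log2 scale), which argues against it. Upper-quartile factors left 68 of 76 oxidative phosphorylation genes lower (median -0.49) and 14 macrophage markers higher. The factors moved the median of all genes only from -0.02 to -0.07 and could not decide on scaling. A changed share of macrophages, a lower yield of adipocyte RNA and a diet effect within cells stay open and were not tested.

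Other splits of the libraries into groups of the same sizes were fitted alike, 100 per comparison with the real one included. Splits with as many genes called were rare in all 6 comparisons, but a state shared by part of a group was not excluded. In liver 1 split each reached the real 4891, 3176 and 735 (HF against LF, HFLF against LF and HFLF against HF). The highest others gave 1734, 1065 and 1. In eWAT 1, 2 and 1 splits reached the real 6817, 94 and 4242, and the highest others gave 3058, 205 and 1260. For the number of lists called, chance could not be excluded. As many lists were called in 84, 70 and 41 splits in liver (9, 9 and 14 real, highest other 21, 20 and 21) and in 35, 19 and 36 in eWAT (20, 18 and 20 real, highest other 27, 27 and 31).

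The 60 splits for overlaps and for genes that turned back also undo the HF effect, so they cannot test either given the HF calls. In liver 1 split gave the real 2177 and 478 genes (highest others 77 and 0). In eWAT 2 splits gave an overlap of 85 or more (highest other 1285), and 1 the real 3620 genes turned back (highest other 0). Why the eWAT splits with 205 and 1285 genes lay above the real counts was not tested. For the differences between tissues, 1 of 50 splits gave the real 6019 and 1130 genes (highest others 2199 and 940).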

How the results depend on the processing

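The fits without named sets of libraries, limma voom without a block between tissues and the splits of the HF libraries were chosen after the results were seen, and the other alternatives before. Values are given in the order HF against LF, HFLF against LF and HFLF against HF. With size factors of the DESeq2 type, upper-quartile factors, a mean CPM of at least 5 or no robust estimation, the number of genes called stayed within 1.5 times in all 6 comparisons. The filterByExpr filter removed no gene. Upper-quartile factors moved the share of higher genes among those called from 46.9% to 61.2%, from 45.1% to 61.7% and from 41.8% to 41.2% in liver, and from 50.5% to 43.8%, from 60.6% to 67.7% and from 42.1% to 53.6% in eWAT. They moved the median log2 fold change of all genes by at most 0.07.

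A log2 fold change of at least 1 left 906, 567 and 111 genes in liver and 2428, 31 and 1261 in eWAT, fewer by construction. limma-trend on the table named RPKM, whose lengths belonged to other genes, called 4, 4 and 1 genes in liver and 88, 2 and 2 in eWAT. It was not run for the named genes. In liver HFLF against HF, DESeq2 called 1312 genes, limma voom 1758, the fit of only the 2 groups 1181, the replicate block 444 and the fit without LF libraries 1 to 4 1355. In eWAT HFLF against LF these were 704, 679 and 50 genes, with 15 for the replicate block, and 6 without the 6 libraries set aside. The causes were not tested. In liver, 297 and 26 genes were called against LF without LF libraries 1 to 4, and 2742 and 1396 without LF libraries 1 and 2, with fewer samples left. Without the 6 eWAT libraries, 1390 genes were called for HFLF against HF.

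Camera with an estimated correlation called 0 lists in all 6 comparisons, with 0, 1 and 4 lists in liver and 3, 2 and 2 in eWAT at an unadjusted p under 0.05. Fry called 4 lists in liver HFLF against HF, and 0 in eWAT HFLF against LF, with 6 at an unadjusted p under 0.05. The causes were not tested. The liver overlap was 20 without LF libraries 1 to 4, 819 without LF libraries 1 and 2, and 731 with 3 LF libraries per comparison. In eWAT the overlap was 561 with DESeq2, 13 with the replicate block, 6 without the 6 libraries and 0.5 with 3 LF libraries per comparison. The number of HF calls that turned back in liver was 803 with DESeq2, 278 with the replicate block, 136 without LF libraries 1 to 4 and 33.5 with 3 HF libraries per comparison. In eWAT it was 1190 without the 6 libraries and 1704 with 3 HF libraries per comparison. With limma voom, 5752 and 924 genes differed between tissues with the number as a block and 5579 and 773 without it (6019 and 1130 in edgeR). Without the libraries in doubt of both tissues, 2502 and 14 genes differed between tissues (HF and HFLF against LF). Fewer libraries were used in these fits.

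Leaving out 1 library at a time, edgeR called 3786 to 5473, 2130 to 3918 and 215 to 1036 genes in liver, and 5845 to 7113, 0 to 341 and 3075 to 5314 genes in eWAT. The lists called numbered 9 to 12, 9 to 13 and 12 to 17 in liver, and 17 to 22, 15 to 22 and 18 to 22 in eWAT. The overlap ranged from 1375 to 2890 genes in liver and from 0 to 309 in eWAT, and the HF calls that turned back from 150 to 690 and from 2664 to 4511.

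Some named genes and lists changed direction, and the causes were not tested. In liver without LF libraries 1 to 4, Mt2 (1.81), Cxcl1 (0.75), Saa2 (2.80) and Mt1 (2.19) did for HF, with the acute phase list (adjusted p = 0.558), and Mt1 (0.65), Fasn (-0.003) and Cidec (0.13) for HFLF, with the let-7 target list (adjusted p = 0.511). Cidec (0.16) and Ppargc1a (0.10) did so for HFLF without LF libraries 1 and 2. Ppargc1a stood there at 0.021 with upper-quartile factors, 0.11 with limma voom and -0.20 to 0.055 without 1 library, and Fasn at -0.026 to 0.26 without 1 library. The de novo lipogenesis list pointed higher for HF without HF library 5 (adjusted p = 0.872, and up to 0.967 without 1 library). In liver HFLF against HF, Cyp7a1 stood at 0.25 with limma voom, 0.055 with the replicate block and -0.33 to 0.31 without 1 library. In eWAT HF against LF, Akr1b7 stood at 0.10 with limma voom, and at 2.34 without the 6 libraries, where Hnf4a stood at 0.42. In eWAT HFLF against LF, Adipoq stood at -0.039 without the 6 libraries, and without 1 library Fasn stood at -0.34 to 0.17 and Dicer1 at -0.064 to 0.007. The let-7 target list pointed lower there by fry (adjusted p = 0.915), without the 6 libraries (0.737) and without HFLF library 4 (0.924, in a range of 0.673 to 0.989 without 1 library). Differences between tissues turned for Myo15b (1.18), Mt2 (-1.53) and Cxcl1 (-1.08) without the libraries in doubt of both tissues.

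Over the named genes and all alternatives, 5482 fits kept the direction and the side of the threshold, 417 lost only the call, 34 gained it and 31 changed direction, 8 of these from a call. For the lists these were 1448, 68, 4 and 6.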

Other observations

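No test was made in this part, and the lists were set before the data were examined. The list of testis and germ cell markers, with 16 measured genes, differed widely between eWAT libraries. Its mean was 6.11 log2 CPM in HF library 1, 4.61 in LF library 4, 4.49 in HFLF library 6, 3.31 in LF library 5 and 3.09 in LF library 2, and between -1.38 and 2.30 in the other 13 eWAT libraries. Of the epididymis markers 2 genes were measured, and their mean was 2.83 in HF library 1 and 2.28 in LF library 3.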
